A study of Astyanax mexicanus with 6 samples.

How the data were processed

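The data were droplet single-cell RNA libraries from the ovaries of 6 adult Mexican tetras (Astyanax mexicanus), 2 each from the Surface, Pachón and Molino populations. Per the labels, each library came from the left ovary of 1 fish of about 520 days, fish were matched for age and had been fasted for a day, and libraries were made with 10x Genomics chemistry. Per the labels' protocols, tissue was digested with collagenase and hyaluronidase for 35 to 45 min, the time depending on the sample, and then with TrypLE. The suspension was passed through 70 and 40 µm filters, so large cells such as late oocytes were removed before capture. The replicate is therefore the fish, and p-values of genes and of cell shares are about the spread between fish. Camera, a test of gene lists described below, sets list members against other genes. With its preset correlation its p-values are not about that spread.

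The authors' deposited values were whole-number UMI counts per gene and barcode, not normalised. They were made with Cell Ranger 7.1.0, per the submitters' processing notes, and each matrix came with the authors' barcode list. The genome build, the annotation release and the treatment of intronic reads are not given in the sources used here. The files listed 27420 genes by Ensembl identifier, of which 16752 had a symbol, and 1887 identifiers shared a symbol with another. Genes that share a symbol may be near-identical copies, so they are left out of the named genes below. Gene positions are not used here, because 0 identifiers matched the reference gene table by Ensembl identifier. Symbols in the files follow zebrafish usage in lower case or human usage in capitals and are printed as given.

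The choices in this paragraph, the gene lists, the marker lists, the tests and the rule for named genes were made before the data were examined, except where stated. Of 19189 barcodes, 930 with fewer than 200 detected genes were removed. Doublets were scored with Scrublet in each library, as implemented in scanpy 1.11.5. The top-scoring share, set beforehand at 0.8% per 1000 barcodes, was removed, which took out 519 barcodes and left 17740 cells. Scrublet's automatic threshold would have marked at most 0.129% of the barcodes of a library, which is too few to have worked. A planned limit of 20% of UMIs from mitochondrially encoded genes could not be applied, because 0 such genes were named in the files, and the list of mitochondrial genome transcripts was void for the same reason. Counts were scaled to 10000 UMIs per cell and log-transformed. Clusters were built from 2000 variable genes, 30 principal components and 15 neighbours with Leiden clustering at resolution 1 (leidenalg 0.10.2), with no integration across libraries, which gave 33 clusters.

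Clusters were named after the data were examined, from the fixed marker lists. A cluster with fewer than 3 raised markers, or led by genes that go against a name, stayed unnamed. Follicle cells fell into separate clusters by population, so 3 clusters with high gsdf, a follicle cell marker of fish, were joined into gsdf-high follicle-like cells. Another 3 clusters with high lhcgr, the luteinising hormone receptor gene, held among their 10 leading genes a marker of another class and none of the follicle class. They carry no type name and are called lhcgr-high cells. They may hold follicle and other steroid-making cells. The genes gsdf and lhcgr define these groups and are not reported as findings in them. Clusters were also built after Seurat 5.3.0 RPCA integration as an alternative. These were named a second time, after results with a first naming had been seen, because the clusters changed with the settings of the numerical library and the first naming had counted a cluster with low gsdf as gsdf-high.

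UMI counts were summed per fish and class. A class was tested where every fish had at least 50 cells, which held for gsdf-high follicle-like, lhcgr-high and macrophage-like cells. Theca-like cells, with at least 20 cells in every fish, were added after the data were seen. Sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by population, quasi-likelihood test) with all 6 fish in 1 fit per class, 3 residual degrees of freedom and the contrasts Pachón minus Surface, Molino minus Surface and Pachón minus Molino. P-values were adjusted over genes within a class and contrast by Benjamini-Hochberg, at a threshold of 0.05. Adjusted p in the text is this value unless camera or fry is named. Robust estimation was chosen among fit settings on simulated data alone. Fold changes are log2 values with a standard error from the quasi-likelihood F. CPM values are means of the 2 fish of a population with their SD. Where a population had no UMI of a gene, the fold is a bound computed from 3 counts over that population's 2 fish. Shares of cells were tested with edgeR on cells per class and fish, and with exact permutation of the fish, which cannot give a p under 0.0667 for both caves against Surface or under 0.333 for 2 against 2 fish. Binomial intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only.

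Tested were 21 fixed gene lists: steroid hormone synthesis, gonadal hormones and their receptors, insulin and IGF signalling, sphingolipid metabolism, cholesterol synthesis and uptake, lipoprotein and fatty acid handling, egg coat and oocyte maternal genes, meiosis, immediate early and heat shock genes, circadian clock, light-inducible DNA repair, hypoxia response, antigen presentation, inflammatory cytokines, interferon response, prostaglandin and ovulation genes, extracellular matrix, mitochondrial genome transcripts, nuclear oxidative phosphorylation, cell proliferation and erythrocyte transcripts. Lists with at least 5 tested members went through camera with its preset correlation of 0.01, adjusted over lists and both contrasts within a class. Camera with an estimated correlation and fry (limma 3.58.1) were alternatives. With an estimated correlation 0 lists passed in any class, against 12, 7, 9 and 5 with the preset value in the gsdf-high, lhcgr-high, macrophage-like and theca-like cells. That version tests on the 3 residual degrees of freedom, so few lists can pass. In Molino the estimate for oxidative phosphorylation was 0.152 in gsdf-high and 0.0131, near the preset, in lhcgr-high cells. In the latter the camera adjusted p still went from 4.93e-19 to 0.126. A loss there alone does not tell a correlated list from a weak test. Adjusted p with an estimated correlation is given beside the calls. Medians of the lists reported did not move where members without UMIs in a population were set at their bound.

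Genes were named by a fixed rule. Per class it took the 5 highest and 5 lowest genes with a symbol that passed in both caves, ranked by the smaller change, then up to 4 members per list with the smallest adjusted p. It also took a fixed set of hormone axis genes whatever their p, the 3 highest and 3 lowest that passed in 1 cave only, and the 3 highest and 3 lowest between the caves. Some genes that the rule takes are not reported here. Markers of other classes are given beside the groups they move with.

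The tests were checked on simulated counts drawn from the real means and library sizes. In each class 200 genes were changed between Pachón and Surface, some 2-fold and some 4-fold. Of those changed 4-fold, 33.0% were recovered in gsdf-high cells (10330 genes tested) and 37.4% in lhcgr-high cells (12594). In macrophage-like cells it was 4.44% (4159) and in theca-like cells 6.67% (2878). Of those changed 2-fold, 2.13%, 2.04%, 0% and 0% were recovered in these classes. The false share of calls was then 26.1% (12 of 46 calls), 18.8% (9 of 48), 20.0% (1 of 5) and 14.3% (1 of 7), above the threshold asked. Each class had a single simulated set. In macrophage-like and theca-like cells the calls were too few to place the false share. With 2160, 2608, 960 and 640 genes changed, 4-fold changes were recovered for 70.1%, 58.4%, 21.5% and 56.0%. Recovery of 2-fold changes was then 11.3%, 7.68%, 3.98% and 4.07%, and the false share was 4.18%, 4.59%, 5.13% and 3.85%. An 8-fold rise of the theca-like share in Pachón was recovered in 46.5% of 200 simulations. The dispersion there was set to 0.3 and not estimated from the fish, so recovery in the real shares may be lower.

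Alternatives were DESeq2 size factors in edgeR, no low-count filter, DESeq2 1.42.0, a replicate block, each fish left out in turn, doublet-scored barcodes kept, at least 500 genes per cell, integrated clusters, sums thinned to the smallest total, and fits on the 4 fish compared. Macrophage-like cells of a single cluster, integrated clusters with a mixed cluster joined to gsdf-high cells, and share denominators without blood and immune or liver-like cells, were added after the data were seen. The libraries follow a numbering in 3 series, each of 1 population, so library batch and population cannot be told apart. Python 3.11.15 and R 4.3.3 were used.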

Results

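Ovaries of surface-dwelling and cave-dwelling Astyanax mexicanus were profiled cell by cell. The species has eyed river populations, called Surface here, and blind cave populations, of which Pachón and Molino were sampled. The comparisons ask how ovarian cell types and their transcripts differ between cave and surface fish, and between the caves. Each population had 2 fish. The 6 matrices held 1134 to 5581 barcodes and 3958093 to 46617496 UMIs. Molino replicate 2 was the shallowest, with 1101 kept cells at a median of 2405 UMIs. The other 5 fish gave 2152 to 4813 kept cells at medians of 3313 to 5760 UMIs. As a check for a library present more than once, the chi-square per degree of freedom over genes between the fish of a population was 534.7 in Surface, 144.2 in Pachón and 69.4 in Molino over all barcodes, which includes differences in cell make-up, and 19.99, 39.5 and 5.89 within gsdf-high cells. Each fish was counted as its own replicate.

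The cells formed germ, oocyte, follicle, theca, stromal, muscle, vascular, blood and immune groups. Gsdf-high follicle-like cells made up 23.1 and 8.79% of kept cells in the Surface fish, 27.1 and 22.9% in the Pachón fish and 16.7 and 13.1% in the Molino fish. Lhcgr-high cells made up 26.1 and 10.2%, 16.5 and 24.2%, and 23.5 and 58.5%. Each population had its own cluster in both groups. Among gsdf-high cells, cluster 7 was mostly Surface, cluster 0 mostly Pachón and cluster 9 mostly Molino. Among lhcgr-high cells these were clusters 4, 1 and 2. Unnamed clusters held 24.97 and 18.41% of the cells of the Surface fish, 11.06 and 5.37% in the Pachón fish and 8.35 and 8.81% in the Molino fish. Both Surface fish thus had more unnamed cells than every cave fish. Shares are of all kept cells, so this leaves less room for named classes in Surface. Shares with unnamed cells left out were not tested.

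Theca-like cells, the steroid-making layer around the follicle, and endothelial-like cells of the vessels had higher shares in all 4 cave fish than in both Surface fish. Theca-like cells were 1.02 and 0.873% of Surface cells, 5.16 and 2.81% of Pachón cells and 1.94 and 2.45% of Molino cells. Endothelial-like cells were 1.35 and 1.25%, 4.69 and 3.43%, and 7.40 and 2.63%. The exact permutation p of both caves against Surface was 0.0667 for each, the smallest that 15 splits can give, and 0.5 after adjustment. In edgeR the theca-like share was 4.19-fold higher in Pachón than in Surface (log2 2.07 ± 1.00) and the endothelial-like share 3.87-fold higher in Molino, and neither passed.

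Macrophage-like cells were 8.86 and 38.02% of Surface, 7.25 and 11.8% of Pachón and 4.69 and 5.54% of Molino cells, so Surface replicate 2 stood apart. Germ cells were 5.17 and 0.104%, 1.12 and 0.640%, and 0.293 and 0.454%. Oocytes were 4.87 and 0.706%, 5.58 and 7.40%, and 1.32 and 1.18%. Stromal fibroblast-like cells were 0.725 and 6.48%, 4.60 and 6.19%, and 11.8 and 3.27%. Liver-like cells with high apoa2 were 9.67% of Molino replicate 1 (95% interval 8.59 to 10.8%) and 0 in every other fish, where 3 cells, taken as the limit that a count of 0 allows, would be 0.0623 to 0.272%. In edgeR 0 of the 45 share tests over 15 classes passed, and 3 had an unadjusted p under 0.05, for epithelial-like cells in Pachón and liver-like cells in Molino against either population. Without Molino replicate 2, those 3 passed. By exact permutation, which cannot pass in this design, 0 passed. Suspensions had passed 70 and 40 µm filters before capture, which limits oocyte shares to cells small enough to pass.

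**Figure D1:**
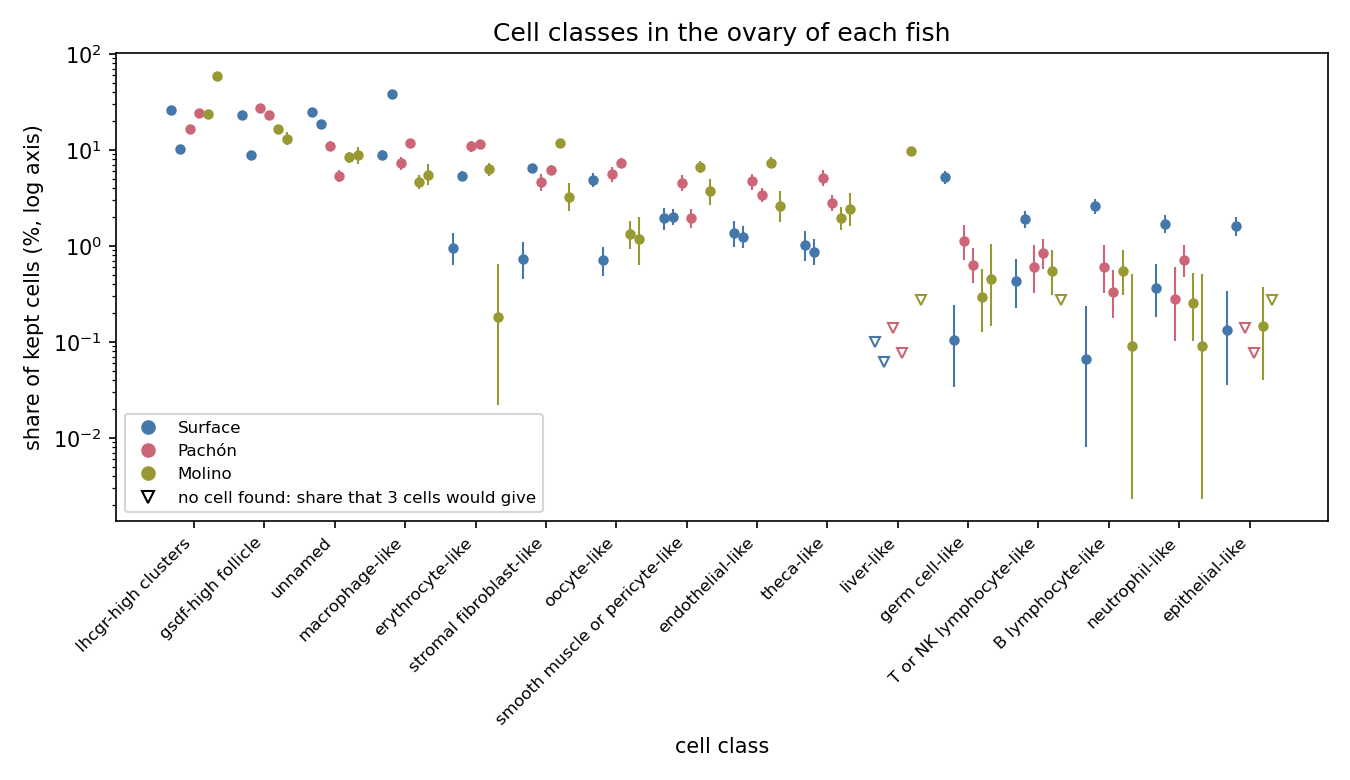
Share of kept cells (%) in each fish for the named cell classes, 1 point per fish, coloured by population (Surface, Pachón, Molino). Macrophage-like cells reach 38.02% in Surface replicate 2, and theca-like and endothelial-like shares of all 4 cave fish lie above both Surface fish.

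In gsdf-high follicle-like cells, both cave populations had lower transcripts of the mitochondrial respiratory chain and of antigen processing than Surface, and higher transcripts of insulin and IGF signalling and of the circadian clock. These are camera calls with a preset correlation, and each was lost with an estimated correlation (adjusted p = 0.401 for the lower lists and 0.507 for the higher ones). In Pachón minus Surface 2206 of 10813 tested genes passed, 1096 higher and 1110 lower. In Molino minus Surface 2007 passed, 921 higher and 1086 lower. Both caves shared 372 higher and 539 lower genes, and 36 went opposite ways. Lists of these sizes would share 93.4 and 111.5 genes if independent. Unchanged groups simulated with a shared Surface group had 0.5 and 0.2 genes in common. With no gene changed few can pass, so that overlap is low by construction. It gives no expected overlap for lists of these sizes. Fold changes of the caves correlated across genes at r = 0.53, against 0.49 in the simulation. Their covariance was 1.44 against 0.19. The simulation holds the shared Surface fish at the fitted spread. Part of the excess may still come from these fish where their real spread is larger. This was not checked, since splitting 2 Surface fish leaves 1 for each cave. Surface values rest mostly on cluster 7, Pachón on cluster 0 and Molino on cluster 9.

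The Molino counts rested on both Molino fish. Without Molino replicate 1, which leaves the shallowest library, 1 gene passed in Molino minus Surface, and without Molino replicate 2, 92 passed. Of 62 calls of named genes there, 0 and 4 were kept. The Pachón count was 1458 without Surface replicate 1, 1029 without Pachón replicate 1 and 908 without Pachón replicate 2. With clusters built after integration across libraries the counts were 1420 in Pachón, 1272 in Molino and 471 shared with a mixed cluster of low gsdf left out, and 2347, 2125 and 891 with it joined to the gsdf-high cells. The Molino count without Surface replicate 1 was 1221. The shared count was 520 without Surface replicate 1, 398 and 349 without Pachón replicates 1 and 2, and 0 and 51 without Molino replicates 1 and 2.

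Several genes were almost silent in Surface or in both caves. The genes rnf34a, IRS1, ccn2b and TPPP had 0 UMIs in Surface gsdf-high cells. Rnf34a, a ubiquitin ligase gene, was at least 24.9-fold higher in Pachón and 9.81-fold higher in Molino (edgeR adjusted p = 0.00162 and 0.00856). IRS1, an adaptor of the insulin and IGF receptors, was at least 14.3- and 11.8-fold higher. The matrix-associated gene ccn2b was at least 7.08- and 18.8-fold higher, and TPPP, which binds microtubules, at least 6.02- and 6.45-fold. In the other direction cyp1b1, a cytochrome P450 that hydroxylates oestrogens, had 28.5 ± 8.53 CPM in Surface (SD, n = 2), 0.0700 CPM in Pachón and 0 in Molino (adjusted p = 0.000404 and 0.00351). The ryanodine receptor gene ryr1b fell from 138 ± 112 CPM to 0.395 and 2.94 CPM. The glucuronyltransferase gene b3gat1a was at least 60.9-fold lower in Pachón and at least 9.74-fold lower in Molino. For calb2a, a calcium-binding protein gene, the bounds were 38.9 and 6.22. The incretin gene gip fell from 28 UMIs in Surface to 1 in Pachón and was at least 6.03-fold lower in Molino.

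**Figure D2:**
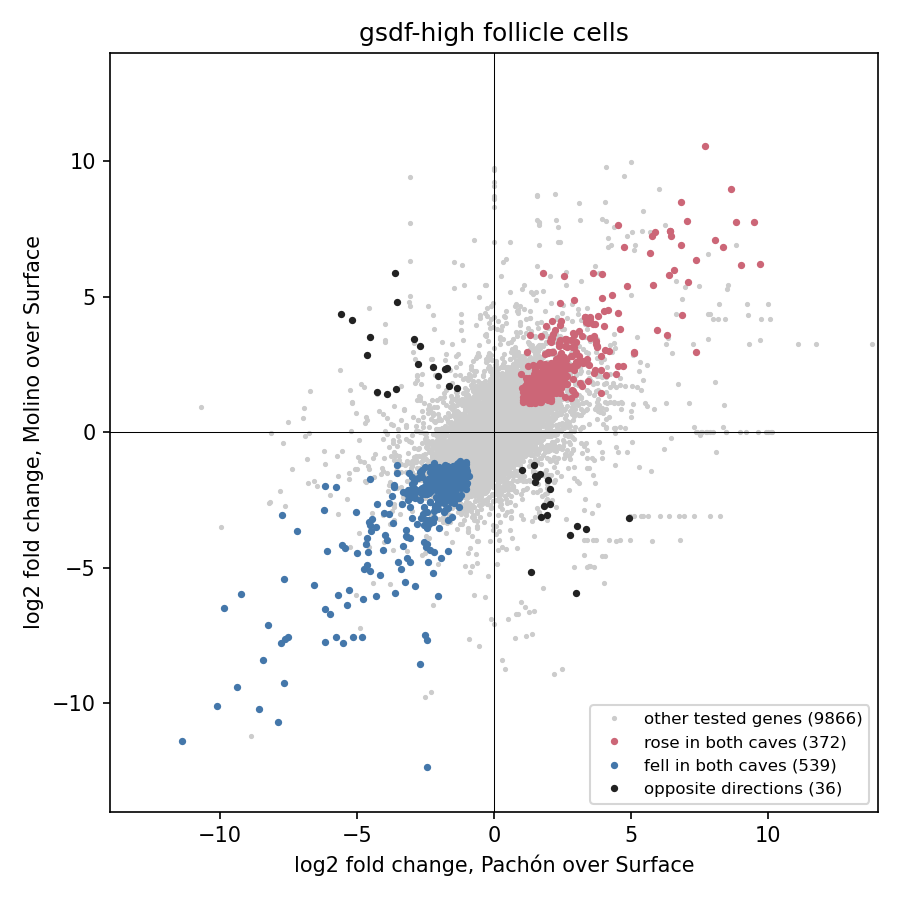
Log2 fold change over Surface in gsdf-high follicle-like cells for every tested gene, Pachón on the x axis and Molino on the y axis, with genes that passed in both caves coloured. Among them 372 lie in the upper right and 539 in the lower left.

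Nuclear genes of oxidative phosphorylation were the list with the most members past the test. Of 84 tested members, 58 fell in Pachón and 69 in Molino, 52 in both, and 0 rose. Adjusted over the list alone, 71 and 74 passed. The median log2 change was -1.42 and -1.57 (camera adjusted p = 2.75e-21 and 2.43e-26). It was adjusted p = 0.401 with an estimated correlation in each cave, and fry gave 0.0205 in each. The cytochrome c oxidase subunit genes cox6c (-2.88 ± 0.37 in Pachón, -2.41 ± 0.37 in Molino), cox7a2a (-2.98 ± 0.35, -2.29 ± 0.35) and cox7a2l (-3.36 ± 0.46, -2.65 ± 0.53) fell. So did the ATP synthase gene atp5pf (-3.63 ± 0.42, -1.93 ± 0.40). Cox6c went from 1437 ± 324 CPM in Surface to 196 ± 34.5 in Pachón and 274 ± 96.4 in Molino.

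**Figure D3:**
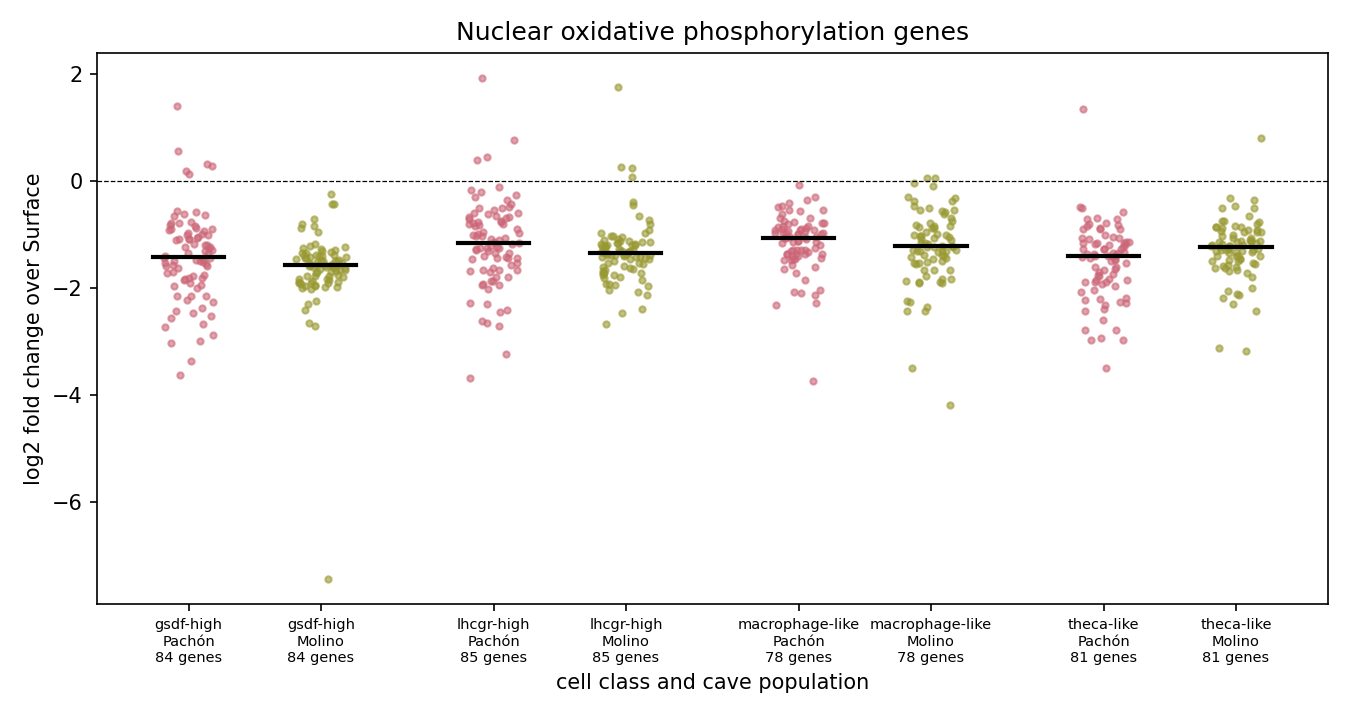
Log2 fold change over Surface of each tested nuclear oxidative phosphorylation gene, by cell class and cave, 1 point per gene with the median as a line. The medians lie between -1.57 and -1.07 in the 4 classes and both caves.

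Insulin and IGF signalling genes were higher as a list. Of 31 members, 8 rose and 1 fell in Pachón, and 8 rose in Molino, 6 of them in both. Adjusted over the list alone, 10 and 8 passed. The camera adjusted p was 0.00792 and 0.00329, with medians of 0.94 and 0.71, fry gave 0.0213 and 0.0362, and adjusted p = 0.507 with an estimated correlation. The IGF receptor gene igf1ra (Ensembl gene ENSAMXG00000020664) rose by 1.98 ± 0.38 in Pachón and 1.51 ± 0.38 in Molino (edgeR adjusted p = 0.00677 and 0.0248). Its level was 48.4 ± 19.6 CPM in Surface, 192 ± 42.7 in Pachón and 139 ± 14.5 in Molino (SD, n = 2). The insulin receptor gene insra (ENSAMXG00000001680) rose by 0.97 ± 0.31 in Pachón and by 2.17 ± 0.32 in Molino, where it was higher than in Pachón (Pachón minus Molino -1.20 ± 0.31, adjusted p = 0.0342). The receptor substrate gene irs2a rose in Pachón (1.99 ± 0.32, adjusted p = 0.00340) and not in Molino (-0.48 ± 0.33, adjusted p = 0.322), and the caves differed (adjusted p = 0.00223). Igf1rb rose in Molino (1.302 ± 0.40), and insrb did not pass in either cave (0.94 ± 0.35 and 0.92 ± 0.36).

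Gonadal hormone genes moved in part. Of 25 members 8 rose and 0 fell in Pachón, and 2 rose and 1 fell in Molino, with 8 and 2 adjusted over the list alone. As a list neither cave passed (camera adjusted p = 0.0940 in each). Fshr, the receptor of follicle-stimulating hormone, rose in Pachón (1.57 ± 0.42, edgeR adjusted p = 0.0254) and was 0.88 ± 0.43 in Molino (adjusted p = 0.171). Amh, the anti-Müllerian hormone gene, rose in Pachón (2.204 ± 0.46), as did the oestrogen receptor gene esr1 (1.40 ± 0.38) and the activin subunit gene inhbb (1.98 ± 0.36). Inha, the inhibin alpha subunit gene, fell in Molino (-2.01 ± 0.45, adjusted p = 0.0163), was 0.70 ± 0.39 in Pachón, and differed between the caves (2.71 ± 0.45). Glucocorticoid receptor gene nr3c1 (ENSAMXG00000011646) rose in both caves (1.35 ± 0.32 and 1.08 ± 0.32). A gene listed with the symbol in capitals, NR3C1 (ENSAMXG00000039789), rose in Pachón (1.95 ± 0.42). Whether it is a second copy was not tested. Esr2a, esr2b, pgr, inhbaa, igf1rb in Pachón and vldlr did not pass. The oestrogen synthesis genes cyp19a1a and hsd17b1 lead these clusters and are not compared.

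Steroid synthesis genes went both ways. Of 15 members 1 rose and 4 fell in Pachón, and 1 rose and 1 fell in Molino, with 5 and 5 adjusted over the list alone. As a list neither passed (camera adjusted p = 0.390 and 0.933), and in Molino the median was -0.38 where the mean was 0.00 and camera pointed up. Nr5a2, a nuclear receptor that drives steroid genes, fell in Pachón (-3.64 ± 0.63, edgeR adjusted p = 0.00538) and was -0.71 ± 0.62 in Molino, a difference that passed (adjusted p = 0.0257). The 3-beta-hydroxysteroid dehydrogenase gene hsd3b2 fell in both caves (-1.25 ± 0.32 and -1.06 ± 0.33). It is highest in theca-like cells, at 4097 CPM against 523 CPM in Surface gsdf-high cells. Hsd17b4 fell in Pachón (-1.55 ± 0.36). Hsd3b7 rose in both caves (2.84 ± 0.49 and 3.17 ± 0.52) from 1.92 CPM, and is highest in neutrophil-like cells. Cyp17a1 did not pass.

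The circadian clock list was higher in both, with 5 of 33 members rising in Pachón and 5 rising and 1 falling in Molino, 3 rising in both, and 5 and 10 adjusted over the list alone. The camera adjusted p was 0.0396 and 0.0292, and adjusted p = 0.507 with an estimated correlation, and fry gave 0.0968 and 0.117. The Pachón call was lost without a low-count filter (0.0510), and without Surface replicate 1 (0.198), Pachón replicate 2 (0.251) or Molino replicate 1 (0.0612). The Molino call was lost without Surface replicate 1 (0.172) or Molino replicate 1 (0.212). The period gene per1a rose in both (2.57 ± 0.45 and 1.99 ± 0.46), nr1d4b, of the REV-ERB family, in Pachón (3.97 ± 0.43, edgeR adjusted p = 0.000579), dbpb in Pachón (1.64 ± 0.42) and tefa in Molino (2.27 ± 0.51).

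Immediate early and heat shock genes were higher in Pachón. There 15 of 42 members rose and 1 fell (19 adjusted over the list alone, median 0.84, camera adjusted p = 0.00328). Adjusted p = 0.507 with an estimated correlation, and fry gave 0.0537. In Molino 5 rose and 3 fell (8 over the list alone), with a median of -0.27, a mean of 0.01 and a camera adjusted p of 0.963. The AP-1 gene fosb (2.13 ± 0.31 and 1.51 ± 0.30) and the cytokine inhibitor gene socs3a (2.197 ± 0.35 and 1.77 ± 0.37) rose in both caves, klf6a in Pachón (2.69 ± 0.43), and the phosphatase gene dusp5 fell in Molino (-2.25 ± 0.31). These genes respond to tissue dissociation, whose time varied between samples. Of hypoxia response genes 4 rose and 4 fell in Pachón and 3 and 5 in Molino, of 30 (9 and 10 over the list alone), and the list did not pass (camera adjusted p = 0.984 and 0.211). The glycolytic regulator pfkfb4b rose (from 0.525 to 9.39 CPM and from 0.525 to 3.87 CPM) and the glycolytic enzyme gene pgk1 fell (-1.65 ± 0.31 and -1.62 ± 0.34). Of 6 light-inducible DNA repair genes 0 passed in either cave in edgeR or DESeq2, with 1 and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.390 and 0.933, with a Molino median of -0.19 where camera pointed up).

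Antigen presentation genes were lower in both caves. Of 11 members 6 fell and 1 rose in Pachón and 5 fell in Molino, 3 in both (8 and 6 adjusted over the list alone). Camera gave adjusted p = 0.00410 and 0.00401, fry 0.0205 in each, and adjusted p = 0.401 with an estimated correlation in each. The proteasome activator genes psme1 (-2.32 ± 0.35 and -1.27 ± 0.35) and psme2 (-2.10 ± 0.35 and -1.89 ± 0.37) and the chaperone gene pdia3 (-2.04 ± 0.35 and -1.59 ± 0.35) fell in both, and the immunoproteasome gene psmb9a in Pachón (-1.98 ± 0.34). Psme1, psme2 and psmb9a are proteasome genes. Proteasome subunit genes, a family chosen after the result was seen, fell for 34 of 45 members in each cave (medians -1.39 and -1.60). The lower antigen presentation list is thus not set apart from that family. The chemokine gene ccl19a.1 fell from 313 ± 109 CPM to 15.8 in Pachón and 3.98 in Molino. It is highest in macrophage-like cells, at 595 CPM. Macrophage-high fabp4a, at 9974 CPM in those cells, fell with it in gsdf-high cells (-2.98 ± 0.55 and -2.38 ± 0.55), and macrophage-like cells were most numerous in Surface replicate 2. As a list inflammatory genes did not pass in camera (adjusted p = 0.814 and 0.0629), while fry gave 0.406 in Pachón and 0.0205, lower, in Molino. Of 15 inflammatory genes 4 rose and 3 fell in Pachón, and 0 rose and 5 fell in Molino (8 and 5 over the list alone). Nfkbiab rose in Pachón (1.498 ± 0.31) and mif fell in Molino (-1.43 ± 0.34). Interferon response genes rose for 4 of 9 members in Pachón with 1 falling (rsad2, -2.195 ± 0.47), and 1 fell in Molino (6 and 3 over the list alone, camera adjusted p = 0.211 and 0.933).

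Extracellular matrix genes were higher in Molino, where 8 of 23 members rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 0.00221, adjusted p = 0.507 with an estimated correlation, fry 0.0546). In Pachón 2 rose and 1 fell (3 over the list alone, camera adjusted p = 0.740), with a median of 0.36 and a mean of -0.26. Basement membrane gene agrn (2.02 ± 0.36 and 2.09 ± 0.37) and microfibril gene FBN1 (1.43 ± 0.36 and 1.86 ± 0.38) rose in both caves, and lama5 in Molino (1.92 ± 0.37). The collagen cross-linking gene loxa fell from 21.3 CPM to 0.250 and 0.230 CPM. Among prostaglandin and ovulation genes 2 rose and 2 fell in Pachón and 1 and 3 in Molino, of 17 (6 and 5 over the list alone, camera adjusted p = 0.619 and 0.918). NR4A1 rose (1.503 ± 0.36 and 1.80 ± 0.38) and the protease gene ADAMTS1 fell (-1.93 ± 0.49 and -2.13 ± 0.60) in both, and the cyclooxygenase gene ptgs2b fell in Molino (-1.31 ± 0.34).

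Lipid genes showed few shared changes. Of 26 sphingolipid genes 3 rose in Pachón, and 3 rose and 2 fell in Molino (3 and 6 over the list alone, camera adjusted p = 0.735 and 0.933). The sphingomyelin synthase gene sgms1a rose in both (1.46 ± 0.35 and 1.88 ± 0.37). Asah1b, an acid ceramidase gene highest in macrophage-like cells, fell in Molino (-1.90 ± 0.40). Of 17 cholesterol genes 0 passed in either cave in edgeR and 1 and 0 in DESeq2, with 6 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.527 and 0.814). Of 36 lipoprotein and fatty acid genes 4 rose and 5 fell in Pachón and 3 and 3 in Molino (9 and 5 over the list alone, camera adjusted p = 0.691 and 0.711). Fabp7a rose in Molino (from 0.165 to 7.73 CPM) and plin2, a lipid droplet coat gene highest in macrophage-like cells, fell in Molino (-2.31 ± 0.33). Egg coat genes, of 14 tested, passed for 0 in either cave in edgeR or DESeq2, with 0 and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.527 and 0.152).

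Proliferation genes were lower in Pachón, with 4 of 34 falling and 3 adjusted over the list alone (camera adjusted p = 0.00401, and adjusted p = 0.792 with an estimated correlation and 0.335 in fry), a call lost without Surface replicate 1 (0.260). In Molino 2 fell and 0 passed adjusted over the list alone (camera adjusted p = 0.112). The condensin gene ncapg fell in both (-2.05 ± 0.50 and -2.07 ± 0.61), ncapd2 and smc2 in Pachón (-1.78 ± 0.46 and -2.34 ± 0.52) and pcna in Molino (-1.23 ± 0.33). Smc2, ncapg and ncapd2 are highest in germ cells, which were most frequent in Surface replicate 1. Erythrocyte transcripts were lower in Pachón, with 2 of 5 falling (2 over the list alone, camera adjusted p = 0.0267, and adjusted p = 0.579 with an estimated correlation and 0.108 in fry), and the call was lost without Surface replicate 1 (0.0539). In Molino 1 fell (2 over the list alone, camera adjusted p = 0.0541). These were the carbonic anhydrase gene cahz (-3.55 ± 0.59 in Pachón) and blvrb (-2.01 ± 0.38 and -1.56 ± 0.41), while erythrocyte-like cells were 0.955 and 5.38% of Surface and 10.9 and 11.4% of Pachón cells.

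**Figure D4:**
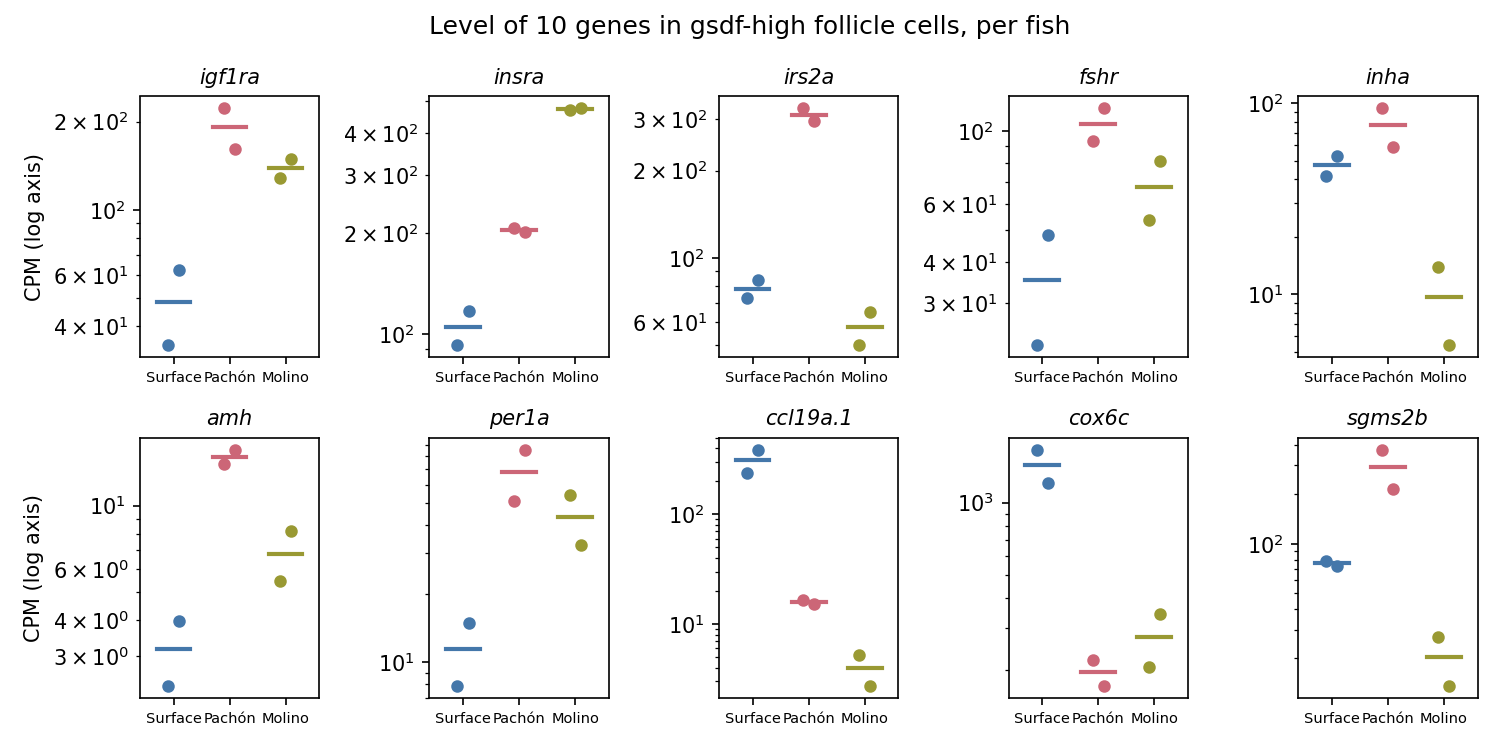
Level (CPM, log axis) of 10 named genes in gsdf-high follicle-like cells, 1 point per fish, by population. Igf1ra and insra are higher in all 4 cave fish than in both Surface fish, cox6c and ccl19a.1 lower in all 4.

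The caves also differed from each other in gsdf-high cells. In Pachón minus Molino 1062 genes passed, 582 higher and 480 lower in Pachón. The count was 34 without Molino replicate 1, 252 without Molino replicate 2, 643 without Pachón replicate 1 and 561 without Pachón replicate 2. Of these calls 54.8% were higher in Pachón with all fish, and 32.4 and 47.2% without Molino replicates 1 and 2. Of 34 calls of named genes, 3 and 17 were kept without Molino replicates 1 and 2. The potassium channel gene kcnn1b was at least 49.8-fold higher in Pachón, and the neuropeptide Y receptor gene npy2rl at least 111-fold higher in Molino (edgeR adjusted p = 0.000404 and 0.00141). Some genes passed against Surface in 1 cave and differed between the caves. PLPPR2 was at least 119.8-fold higher in Pachón than in Surface, at 52.8 CPM against 0.115 CPM in Molino. Sema3d, a guidance factor gene, fell in Pachón (-7.52 ± 0.65) and was 0.37 ± 0.47 in Molino. In Molino bzw2 (from 97.7 to 0.115 CPM) and the elongation factor gene eef1da (-8.39 ± 0.86, from 529 to 4.41 CPM) fell, against 0.41 ± 0.52 and 0.27 ± 0.51 in Pachón. CBFA2T3 was at least 58.5-fold higher in Molino than in Surface.

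In lhcgr-high cells both caves again had lower oxidative phosphorylation and antigen presentation transcripts than Surface, with higher fshr, esr1, per1a and foxo1b. As lists these are camera calls that were lost with an estimated correlation (adjusted p = 0.186 in Pachón and 0.126 in Molino for oxidative phosphorylation, 0.717 in each for antigen presentation). In Pachón minus Surface 1389 of 13049 tested genes passed, 673 higher and 716 lower, and in Molino minus Surface 1422, 674 higher and 748 lower. Both caves shared 184 higher and 295 lower genes, against 34.8 and 41.0 for independent lists, and 16 went opposite ways. The simulation of unchanged groups, where few genes can pass, shared 0.2 and 0 and gives no expected overlap. The covariance of fold changes was 1.23 against 0.19 simulated, at r = 0.48 in both. Part of the excess may come from the shared Surface fish. Surface values rest mostly on cluster 4, Pachón on cluster 1 and Molino on cluster 2. The Pachón count was 584 and 385 without Pachón replicates 1 and 2 and 894 without Molino replicate 1. The Molino count was 134 and 248 without Molino replicates 1 and 2, 889 without Surface replicate 2 and 874 without Pachón replicate 2. The shared count was 206 and 149 without Pachón replicates 1 and 2 and 61 and 112 without the Molino ones. Of 53 calls of named genes in Molino minus Surface, 9 and 16 were kept without Molino replicates 1 and 2, and 31 without Surface replicate 2. Of 56 in Pachón minus Surface, 32 and 28 were kept without Pachón replicates 1 and 2.

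Cyp1b1 was nearly absent from both caves here too. It went from 105 ± 36.0 CPM in Surface to 0 in Pachón, at least 667-fold lower, and 0.215 CPM in Molino (edgeR adjusted p = 0.00117 and 0.00216). GALNT8, which adds sugars to proteins, fell from 216 ± 56.9 CPM to 0.520 and 0.390 CPM. Gip fell from 281 UMIs in Surface to 1 in Pachón and was at least 58.8-fold lower in Molino. B3gat1a fell (-7.17 ± 0.58 and from 29.4 to 0.0450 CPM) and calb2a was at least 32.3- and 19.2-fold lower. In the other direction TMC8 rose from 0.725 ± 0.0354 CPM to 77.0 ± 48.6 in Pachón and 110.1 ± 37.0 in Molino. The synaptic adhesion gene nlgn2a (5.32 ± 1.29 and 7.24 ± 1.34) and the adaptor gene SHC3 (1 UMI in Surface, 1.56 CPM in Pachón and 2.42 in Molino) rose, and SCRG1 was at least 17.1- and 22.6-fold higher.

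Of 85 oxidative phosphorylation genes 30 fell in Pachón and 35 in Molino, 18 in both, and 0 rose (49 and 72 adjusted over the list alone). The medians were -1.16 and -1.35 (camera adjusted p = 2.62e-15 and 4.93e-19, fry 0.00186 and 0.000419), and adjusted p = 0.186 and 0.126 with an estimated correlation. Cox6c (-2.45 ± 0.41 and -1.95 ± 0.40), cox7a2a (-2.41 ± 0.40 and -1.93 ± 0.39), cox7a2l (-3.69 ± 0.47 and -2.67 ± 0.45) and atp5pf (-3.23 ± 0.44 and -1.72 ± 0.42) fell. Antigen presentation genes were lower, with 1 and 2 of 11 falling (3 and 4 over the list alone, camera adjusted p = 0.0195 and 0.0411, fry 0.0954 and 0.118, and adjusted p = 0.717 with an estimated correlation). This call was lost in Pachón without Surface replicate 1 (0.148) or Pachón replicate 1 (0.0541). In Molino it was lost without Surface replicate 1 (0.315) or 2 (0.0566), or Molino replicate 1 (0.136) or 2 (0.121). Without a low-count filter it was lost in both (0.140 and 0.0704). Psmb10 fell in Pachón (-2.45 ± 0.40) and psme2 and the cathepsin gene ctss2.1 in Molino (-1.89 ± 0.48 and -2.34 ± 0.46). Psmb10 and psme2 are proteasome genes, and the proteasome subunit family had medians of -0.86 and -1.41 here. Macrophage-high ccl19a.1 (-3.32 ± 0.40 and -4.71 ± 0.46) and fabp4a (-4.16 ± 0.57 and -3.23 ± 0.55) fell with the antigen presentation genes.

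Fshr (1.73 ± 0.46 and 2.00 ± 0.47, edgeR adjusted p = 0.0488 and 0.0331) and esr1 (1.77 ± 0.42 and 1.63 ± 0.42) rose in both caves, and esr2a (2.66 ± 0.53) and the steroid hydroxylase gene cyp17a1 (2.602 ± 0.41) in Molino. Cyp17a1 is highest in theca-like cells, at 1861 CPM, whose share was higher in all 4 cave fish. Theca-like cells held it at 4072 and 3213 CPM in the Molino fish and 808 and 1398 CPM in the Surface fish. It stood at 0 to 0.48 CPM in macrophage-like cells. In smooth muscle-like and stromal fibroblast-like cells it stood at 0 and 3.49 CPM in Molino replicate 1, and 268 and 192 CPM in Molino replicate 2. Lhcgr-high cells of these 2 fish held 60.5 and 84.5 CPM. Inhbb (3.23 ± 0.52) and the activin-binding follistatin gene fsta (2.63 ± 0.51) rose in Pachón, inha fell in Molino (-2.16 ± 0.44), and nr5a2 (-3.65 ± 0.46) and hsd17b4 (-1.22 ± 0.32) fell in Pachón. Of 26 gonadal hormone genes 4 rose and 1 fell in Pachón and 3 and 1 in Molino (7 and 4 over the list alone), and the list did not pass (camera adjusted p = 0.280 and 0.325). Esr2b, pgr, amh, inhbaa, cyp19a1a, hsd17b1, igf1rb, insra, insrb and vldlr did not pass. Insulin and IGF genes were higher in Molino, with 8 of 34 rising (11 over the list alone, camera adjusted p = 0.0157, fry 0.0954, and adjusted p = 0.444 with an estimated correlation), a call lost without Surface replicate 2 (0.0684). In Pachón 4 rose and 1 fell (6 over the list alone, camera adjusted p = 0.280). The transcription factor gene foxo1b (2.41 ± 0.42 and 2.42 ± 0.43) and IRS1 (2.32 ± 0.49 and 2.58 ± 0.50) rose in both, igf1ra in Pachón (1.37 ± 0.37) and igf2r in Molino (2.48 ± 0.47).

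The clock list was higher in Molino (4 of 36 rising, 4 over the list alone, camera adjusted p = 0.0206, fry 0.0954, and adjusted p = 0.717 with an estimated correlation), a call lost without Surface replicate 1 (0.0716) or Molino replicate 1 (0.136). In Pachón 3 rose and 1 fell (camera adjusted p = 0.280). Per1a rose in both (2.56 ± 0.46 and 2.43 ± 0.46), nr1d4b in Pachón (3.01 ± 0.38), and rorcb (1.95 ± 0.33) and hlfa (1.81 ± 0.43) in Molino. Proliferation genes were lower in Molino by camera (adjusted p = 0.0401), with 0 of 29 members passing in edgeR, 11 at an unadjusted p under 0.05 and 5 in DESeq2, and adjusted p = 0.813 with an estimated correlation and 0.442 in fry. The camera call with the preset correlation was lost without Surface replicate 1 (adjusted p = 0.867) and without Molino replicate 1 (0.386). The other 15 lists tested passed in neither cave, and for meiosis 0 of 7 members passed in edgeR or DESeq2, with 1 in each cave at an unadjusted p under 0.05 (camera adjusted p = 0.404 and 0.585). The median and the camera direction differed in sign for interferon response in Pachón (0.55, camera down) and hypoxia response in Molino (0.09, camera down). Median and mean differed for extracellular matrix in Pachón (0.45 and -0.16) and sphingolipid genes in Molino (-0.44 and 0.02).

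Named members of those lists moved one by one. The lipid gene acsl1b (5.74 ± 0.45) rose and the sterol synthesis gene hmgcs1 (-2.04 ± 0.36) fell in Pachón. SCAP, the sterol sensor partner, fell in both (-2.21 ± 0.43 and -1.67 ± 0.44). The ceramide synthase gene cers4a (from 0.175 to 4.13 CPM) and the mitochondrial regulator gene PPARGC1A (3.44 ± 0.54) rose in Molino. Liver-high apoa2 fell in Pachón (-2.91 ± 0.48). Klf2b (3.28 ± 0.51), the collagen chaperone gene serpinh1b (3.76 ± 0.68) and ero1a (3.07 ± 0.51) rose and dusp5 (-2.43 ± 0.40) fell in Molino. Pfkfb4b (1.87 ± 0.45 and 2.39 ± 0.46) and stat1a (1.54 ± 0.41 and 1.54 ± 0.41) rose and rsad2 (-4.26 ± 0.58 and -2.53 ± 0.54) fell in both. FBN1 rose (4.36 ± 0.45 and 1.81 ± 0.43), while COL5A1 (from 19.6 to 0.0950 CPM and -4.09 ± 1.06) and ADAMTS1 (-2.39 ± 0.62 and -2.602 ± 0.67) fell in both.

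Between the caves 999 genes passed in lhcgr-high cells, 443 higher and 556 lower in Pachón. The count was 437 and 250 without Pachón replicates 1 and 2, and 148 and 366 without Molino replicates 1 and 2. Of these calls 44.3% were higher in Pachón with all fish, 57.2% without Pachón replicate 2, and 22.97 and 34.4% without Molino replicates 1 and 2. Without a low-count filter it was 51.6%. Of 32 calls of named genes, 17 and 13 were kept without Pachón replicates 1 and 2 and 7 and 20 without the Molino ones. HOMER1 and the glutamate transporter gene slc1a2b had 0 UMIs in Surface and Molino and were at least 110.3- and 79.6-fold higher in Pachón than in Molino. Fxyd2, a sodium pump subunit gene, was at least 198-fold and npy2rl at least 75.4-fold higher in Molino than in Pachón. The Wnt inhibitor gene APCDD1 was at least 121-fold lower in Pachón than in Surface and 0.30 ± 0.41 in Molino. RPL22, a ribosomal protein gene (ENSAMXG00000038704), fell in Molino from 1682 ± 1111 to 5.23 ± 3.31 CPM (-8.42 ± 0.90, edgeR adjusted p = 0.00274), with 897 ± 419 CPM in Pachón.

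In macrophage-like cells few genes passed. In Pachón minus Surface 38 of 4800 genes passed, 24 higher and 14 lower, in Molino minus Surface 13, 9 higher and 4 lower, and in Pachón minus Molino 15, 7 higher and 8 lower. Both caves shared 4 higher genes and 1 lower, against 0.04 and 0.01 for independent lists. The simulation of unchanged groups shared 0.05 and 0, which again gives no expected overlap where genes did change. The covariance of fold changes was 1.00 against 0.30 simulated, at r = 0.44 against 0.42. Part of the excess may come from the shared Surface fish. Nocturnin, NOCT, a clock-regulated deadenylase gene, rose from 1.54 ± 0.771 CPM to 26.4 ± 10.7 in Pachón and 106 ± 40.1 in Molino (4.43 ± 0.80 and 6.42 ± 0.84, edgeR adjusted p = 0.0364 and 0.0217). The glycosyltransferase gene mgat4b rose in Pachón (5.59 ± 0.66, adjusted p = 0.00711) and was -0.03 ± 0.71 in Molino, and selenof fell in Pachón (-5.89 ± 0.84). In Molino RPL22 fell (from 1231 to 2.51 CPM). Genes that lead the macrophage-like clusters are not compared. Nme2b.1 stood at 810.0 CPM in Pachón and 2.51 CPM in Molino (Pachón minus Molino, edgeR adjusted p = 0.0294).

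Macrophage-like cells came mostly from clusters 3 and 11 in Surface replicate 2, and from cluster 6 in the others. Without Surface replicate 1 the counts were 381, 539 and 201 for Pachón minus Surface, Molino minus Surface and Pachón minus Molino, and without Surface replicate 2 they were 122, 176 and 233. Without Pachón replicate 1 they were 48, 167 and 71, and without Pachón replicate 2 66, 127 and 17. Without Molino replicate 1 or 2 they were 2, 0 and 0, where 550, 805 and 444 genes had an unadjusted p under 0.05 with all fish and DESeq2 called 121, 125 and 64. The shared count was 174, 37, 12, 23, 0 and 0 with each fish left out in that order. Of 10 calls of named genes in Pachón minus Surface, 6 in Molino minus Surface and 5 between the caves, 0 were kept in edgeR without either Molino fish. In cluster 6 alone, added after the data were seen, 269, 266 and 143 passed. Of the Molino calls 69.2% were higher, against 48.8% in DESeq2 and 80% (4 of 5) with DESeq2 size factors. The share was 37.2% without a low-count filter, 33.6 and 27.8% without Surface replicates 1 and 2, 38.9 and 39.4% without Pachón replicates 1 and 2, and 53.0% in cluster 6 alone. Between the caves 46.7% were higher in Pachón, and 67.7 and 63.5% without Surface replicates 1 and 2, 76.1 and 88.2% without Pachón replicates 1 and 2, and 64.7% without a low-count filter.

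As lists, oxidative phosphorylation genes were lower in macrophage-like cells of both caves (medians -1.07 and -1.22, camera adjusted p = 2.22e-12 and 1.09e-07), and clock genes higher (1.38 and 1.13, camera adjusted p = 1.01e-05 and 0.000119). Immediate early genes were higher in both (camera adjusted p = 0.0143 and 0.0137), insulin and IGF genes in Pachón (0.0246), and antigen presentation (0.0144) and proliferation (0.000759) genes lower in Molino. Adjusted p = 0.833 with an estimated correlation for each of these. Fry gave 0.503 for oxidative phosphorylation, clock, insulin and antigen genes, 0.658 and 0.660 for immediate early and 0.598 for proliferation genes. In edgeR 0 of their members passed over all genes or, but for 1 clock gene in Pachón and 3 in Molino, adjusted over the list alone. At an unadjusted p under 0.05 there were 23 and 21 oxidative phosphorylation, 10 and 5 clock and 6 and 4 immediate early genes in Pachón and Molino, 4 insulin genes in Pachón, and 4 antigen and 7 proliferation genes in Molino. DESeq2 passed 3 and 1, 1 and 3, 2 and 1, 0, 0 and 1 members of these lists in that order. Leaving out fish ended 5 of these calls. Without Surface replicate 2 the immediate early p was 0.430 and 0.381, the insulin p 0.0551 and the antigen p 0.0859. Without Pachón replicate 1 the Pachón immediate early p was 0.311, and without Molino replicate 2 the antigen p was 0.0995. Without Surface replicate 1 the insulin p was 0.0543 and the proliferation p 0.0777, and without Molino replicate 1 the latter was 0.245. Without a low-count filter the Pachón insulin p was 0.0612 and the Pachón immediate early p 0.188.

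Theca-like cells, tested after the data were seen on 27 to 111 cells per fish, had lower oxidative phosphorylation genes and, in Pachón, higher insulin receptor and immediate early genes. As lists these are camera calls that were lost with an estimated correlation (adjusted p = 0.209 and 0.194 for oxidative phosphorylation, 0.570 for insulin and IGF and 0.547 for immediate early genes). In Pachón minus Surface 424 of 3210 genes passed, 228 higher and 196 lower, and in Molino minus Surface 91, 63 higher and 28 lower. Both caves shared 24 higher and 16 lower genes, against 4.47 and 1.71 for independent lists, and 2 went opposite ways. The simulation of unchanged groups shared 0.05 and 0, which gives no expected overlap here either. The covariance was 1.496 against 0.21 simulated, at r = 0.55 against 0.51, and part of the excess may come from the shared Surface fish. NOCT had 0 UMIs in Surface and was at least 6.21- and 7.50-fold higher. The fatty acid binding gene fabp7a (from 1.57 to 57.9 CPM and from 1.57 to 168 CPM), sema6e (from 4.71 to 152 CPM and from 4.71 to 119 CPM), the orphan receptor gene NR4A1 (from 4.04 to 70.5 CPM and from 4.04 to 77.4 CPM), fosb (2.95 ± 0.46 and 2.87 ± 0.46) and MCC (from 2.46 to 30.9 CPM and from 2.46 to 55.7 CPM) rose in both. The glucokinase gene gck (-2.12 ± 0.54 and -3.81 ± 0.76), cox6c (-2.78 ± 0.41 and -2.06 ± 0.42), cox7a2a (-2.59 ± 0.43 and -2.19 ± 0.44) and the mitochondrial import gene TOMM7 (-1.81 ± 0.38 and -2.27 ± 0.45) fell in both.

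Of 81 oxidative phosphorylation genes 32 fell in Pachón and 4 in Molino in theca-like cells (64 and 37 adjusted over the list alone, medians -1.41 and -1.23, camera adjusted p = 2.28e-21 and 2.13e-15, fry 0.0144 in each, and adjusted p = 0.209 and 0.194 with an estimated correlation). In Pachón the insulin and IGF (3 of 15 rose, 6 over the list alone, camera adjusted p = 0.0473, adjusted p = 0.570 with an estimated correlation), immediate early (5 of 31 rose and 1 fell, 8 over the list alone, camera adjusted p = 0.0234, adjusted p = 0.547 with an estimated correlation) and clock lists (2 of 9 rose, 2 over the list alone, camera adjusted p = 0.0254, adjusted p = 0.531 with an estimated correlation) were higher. Fry gave 0.0912 for the insulin and immediate early lists and 0.0511 for the clock list. The immediate early call was lost without Surface replicate 2 (0.166) and the clock call without Pachón replicate 2 (0.0546). Insra (1.67 ± 0.39), irs2a (2.26 ± 0.46), foxo3b (2.12 ± 0.49), inhbb (4.28 ± 0.86), per1a (from 5.61 to 69.4 CPM) and nr1d4b (from 1.57 to 160.4 CPM) rose in Pachón. The steroid genes hsd3b2 and cyp17a1 lead the theca-like cluster, so no test of them is reported there.

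Between the caves 117 genes passed in theca-like cells. Star, which brings cholesterol into mitochondria, was lower in Pachón than in Molino (-2.05 ± 0.39, edgeR adjusted p = 0.0305), and passed against Surface in neither cave (0.569 and 0.0578). Inhbb was higher in Pachón than in Molino (from 7.09 to 148 CPM). Ptn was at least 37.1-fold higher in Pachón than in Surface, and RPL22 (from 1504 to 4.50 CPM) and eef1da (from 792 to 14.2 CPM) fell in Molino. Apoeb, at 23254 CPM in macrophage-like cells, and the muscle actin gene acta2, at 7527 CPM in smooth muscle-like cells, fell in Pachón theca-like cells (-6.19 ± 1.68 and -7.36 ± 1.91), and plin2, macrophage-high, fell in Molino (-4.22 ± 0.80). The gene gsdf, at 222 CPM in gsdf-high cells, rose in Pachón (from 4.93 to 51.4 CPM). Without each fish in turn (Surface 1 and 2, Pachón 1 and 2, Molino 1 and 2) the Pachón count was 275, 76, 111, 140, 440 and 439, and the Molino count 15, 8, 124, 98, 0 and 6. The count between the caves was 240, 203, 62, 95, 0 and 71, and the shared count 10, 5, 24, 22, 0 and 3. Of 41 calls of named genes in Pachón minus Surface, 29, 11, 18, 20, 38 and 39 were kept, and of 18 in Molino minus Surface 3, 2, 16, 16, 0 and 3. For the counts of 0, 966 genes had an unadjusted p under 0.05 in Molino minus Surface and 749 in Pachón minus Molino with all fish, and DESeq2 called 174 and 169.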

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

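The tests of a general fall at matched level, of abundant genes and of library batch, and the interval limits used for free RNA, clock phase and dissociation, were chosen after the result was seen, and the other tests before.

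In gsdf-high follicle-like cells 4 named genes passed against Surface in opposite directions in the 2 caves and also passed between the caves. They were picked by these passes, so the adjusted p-values between the caves given here add no separate support. Sgms2b, a sphingomyelin synthase gene, was 1.96 above Surface in Pachón and -1.75 in Molino, 3.70 apart on the log2 scale (edgeR adjusted p = 0.00106). The adrenomedullin gene adma was 3.23 apart (1.68 and -1.55, adjusted p = 0.000390). Nfkbiaa, an inhibitor of NF-kappa-B, was 3.33 apart (1.505 and -1.83, adjusted p = 0.00141), and the interferon regulatory factor gene irf1b 2.66 apart (1.46 and -1.20, adjusted p = 0.0024). Irf1b also leads a Pachón cluster of these cells. As given above, Molino calls in gsdf-high cells rested on both Molino fish, so the Molino side of these results is not firm. Pachón and Molino values also came mostly from separate clusters.

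Nuclear oxidative phosphorylation genes were lower by camera in both caves in all 4 tested classes, a call lost in each with an estimated correlation (adjusted p = 0.401 in gsdf-high, 0.186 and 0.126 in lhcgr-high, 0.833 in macrophage-like and 0.209 and 0.194 in theca-like cells) and, in macrophage-like cells, in fry (0.503). A fall of all genes of that level alike is argued against. In any of 4 comparisons 0% of 10000 random lists matched on level had a median as low. The genes were drawn independently, so such lists cannot set this list apart from other families that fall together. Proteasome subunit genes also fell in gsdf-high cells (medians -1.39 in Pachón and -1.60 in Molino). A first version matched on gene span as well was void, as 63.1% of members had a span. A few abundant genes taking most of the counts are argued against too, since the share of UMIs outside ribosomal protein genes and the 50 most abundant genes of any fish had a lowest log2 ratio of -0.339 (lowest cave fish against highest Surface fish, over 4 classes and both caves), where the list medians were -1.57 to -1.07 and their bootstrap intervals ended at -0.98 or lower, while a first version without ribosomal protein genes was void. A change in the make-up of follicle cells alone is argued against by 7 of 7 other classes with the list's mean share lower in both caves. Library batch cannot be told apart from population, as 0 of 3 numbering series hold more than 1 population, and population remains an untested biological explanation.

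A second pattern is genes almost without counts in cave fish. In gsdf-high cells 120 genes were at least 16-fold lower in Pachón and 90 in Molino, and 179 and 171 at least 16-fold higher. A strain variant, a gene model difference or a lost gene should act in every cell class. In macrophage-like cells 56.1% of the measurable losses (23 of 41) were at least 4-fold, against 7.49% of all genes measurable there, losses included. The explanation may hold for part of the losses and stays open. It bears on named genes given above that fell in Molino in several classes. These are RPL22 in lhcgr-high, macrophage-like and theca-like cells and eef1da in gsdf-high and theca-like cells. For them a fall in expression was not told apart from such a difference. Free RNA from cells lost in the caves could account for some, and this stays open. Of the 210 losses 24.3% had at least 10 times the level in a class outside the follicle (95% interval 18.6 to 30.7%). Losses were counted per cave, so a gene lost in both caves enters for each, and the interval takes them as independent. Reads were not used here, so variants could not be looked for.

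The third pattern is the clock genes, higher by camera in cave fish in 6 class and cave pairs, a call lost in each with an estimated correlation (lowest adjusted p = 0.507) and in fry (lowest 0.0511). A shift of clock phase, such as another time of tissue collection, would part the arms of the clock, and the activator arm had a lowest median of 0.293 in gsdf-high cells, with an interval of -0.93 to 1.49 over 9 genes that leaves it open. A general rise of induced genes with dissociation could also lift the list, and where the clock list was higher the lowest immediate early median was -0.332 (lhcgr-high, Molino), with an interval of -0.52 to 0.06, and the immediate early list was higher in 4 of the 6 class and cave pairs with a higher clock list. By the point values alone, free RNA, phase and dissociation would each have been argued against. Time of collection is not given in the sources used here, and population remains an untested biological explanation.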

How the results depend on the processing

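The theca-like class, the fit on macrophage-like cluster 6, the naming of integrated clusters and the share denominators without blood and immune or liver-like cells were chosen after the result was seen, and the other alternatives before.

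Counts below are in the order Pachón minus Surface, Molino minus Surface, Pachón minus Molino and both caves. Of 408 calls of genes that the naming rule takes, 402 held with doublet-scored barcodes kept, 393 with DESeq2 size factors, 397 without a low-count filter, 362 of 397 with integrated clusters, 378 of 404 in DESeq2, 374 of 406 with at least 500 genes per cell, 357 of 400 on 4 fish and 210 of 271 after thinning. With a fish left out, 321 of 404 and 306 of 406 held without Surface replicates 1 and 2, 288 and 282 of 408 without the Pachón ones, 166 of 398 without Molino replicate 1 and 218 of 408 without Molino replicate 2. In edgeR macrophage-like cells kept 0 of 10, 6 and 5 calls in the first 3 comparisons without either Molino fish, and theca-like cells 11 of 41 in Pachón minus Surface without Surface replicate 2. Gsdf-high cells kept 3 of 34 between the caves without Molino replicate 1. None of these turned its sign under any alternative run. For the counts that moved by over 1.5 times, given next, the cause was not tested, except that thinning and a left-out fish take away UMIs or samples by construction.

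After thinning to the smallest total, counts were 603, 763, 322 and 296 in gsdf-high cells (2865 genes tested), 0, 2, 0 and 0 in macrophage-like cells (924 tested, edgeR, 99, 154 and 128 at an unadjusted p under 0.05) and 58, 32, 45 and 7 in theca-like cells (848 tested). Without a low-count filter, gsdf-high cells gave 1750 between the caves. Lhcgr-high cells gave 2513, 2745, 1999 and 1003, macrophage-like cells 233, 269, 85 and 42, and theca-like cells 750, 366, 582 and 125, with 13 lists passing there in place of 5. DESeq2 gave 729 shared in lhcgr-high cells, 121, 125, 64 and 28 in macrophage-like cells, and 174 in Molino and 66 shared in theca-like cells. With at least 500 genes per cell, macrophage-like cells gave 67 in Pachón and 8 shared, and theca-like cells 2 in Molino and 1 shared. On the 4 fish compared, macrophage-like cells gave 0, 50, 164 and 0 in edgeR and theca-like cells 211 between the caves. With DESeq2 size factors, macrophage-like cells gave 5 in Molino and 3 shared. With integrated clusters they gave 7 and 3, theca-like cells 139 in Molino, 189 between the caves and 72 shared, and gsdf-high cells 1420 in Pachón, 1272 in Molino and 471 shared. There 9478 genes were tested, and a cluster of 595 cells that joins gsdf-high and lhcgr-high cells was left unnamed. Joined to gsdf-high cells, as in a first naming, it gave 2347, 2125, 1456 and 891, with 11613 genes tested. Macrophage-like cells of cluster 6 gave 269, 266, 143 and 75. Of theca-like Molino calls 69.2% were higher, against 53.4% in DESeq2, 42.3% without a low-count filter and 0 of 2 with at least 500 genes per cell or a replicate block. Without Surface replicates 1 and 2 it was 2 of 15 and 0 of 8, without Pachón replicates 1 and 2 48.4 and 48.0%, and without Molino replicate 2 it was 2 of 6. Of theca-like Pachón calls 53.8% were higher, and 35.5% without Surface replicate 2. Of macrophage-like Pachón calls 63.2% were higher, and 44.3% without Surface replicate 2. Of Molino calls in lhcgr-high cells 47.4% were higher, and 71.6 and 62.1% without Molino replicates 1 and 2. Of Pachón calls there 48.5% were higher, and 59.5% without Pachón replicate 2. Of Molino calls in gsdf-high cells 45.9% were higher, and 35.2% without Surface replicate 1 and 55.4% without Molino replicate 2. Between the caves 47.9% of theca-like calls were higher in Pachón, and 62.5% without a low-count filter, 59.6 and 58.1% without Surface replicates 1 and 2, 61.3 and 64.2% without the Pachón ones, and 39.4% without Molino replicate 2.

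With the replicate number as a block, counts were 850, 679, 637 and 235 in lhcgr-high cells, 80, 44 and 15 (Pachón, Molino, shared) in macrophage-like cells and 119, 2, 34 and 1 in theca-like cells. Of named gene calls 313 of 408 held, and all 33 list calls. Differences between replicates 1 and 2 correlated across genes between populations at -0.22 to 0.52. The highest values were between Surface and Pachón, 0.52 in macrophage-like and 0.21 in theca-like cells. The numbers were treated as names only, and these values do not exclude that they pair the fish.

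List calls held for 33 of 33 with DESeq2 size factors, 28 without a filter, 10 in fry and 0 with an estimated correlation. The last version tests on 3 degrees of freedom, where few lists can pass. Without Surface, Pachón and Molino replicates 1 and 2 in turn, 23, 26, 31, 31, 27 and 31 held. Passing lists in gsdf-high, lhcgr-high, macrophage-like and theca-like cells were 7, 2, 0 and 2 in fry and 0 in each with an estimated correlation, whose lowest adjusted p among called lists were 0.401, 0.126, 0.833 and 0.194. Oxidative phosphorylation adjusted p ranged over all alternatives from 2.20e-29 to 0.401 in Pachón and 1.47e-37 to 0.401 in Molino gsdf-high cells, and stayed at or under 3.15e-15 and 7.17e-23 with the preset correlation.

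Leaving out each fish, where the lone fish is assumed to vary like the others, gave ranges of 908 to 2015, 1 to 1854, 34 to 1518 and 0 to 872 in gsdf-high cells and 385 to 1540, 134 to 1505, 148 to 1401 and 61 to 668 in lhcgr-high cells. The ranges were 2 to 381, 0 to 539, 0 to 233 and 0 to 174 in macrophage-like cells and 76 to 440, 0 to 124, 0 to 240 and 0 to 24 in theca-like cells. Passing lists ranged from 8 to 19, 4 to 8 and 4 to 9 in gsdf-high, lhcgr-high and theca-like cells, and passing shares from 0 to 3. Without Molino replicate 1 the Molino counts were lowest, level with those without replicate 2 in macrophage-like cells. The lone replicate 2 then had 277744 UMIs in gsdf-high and 61796 in macrophage-like cells. The 3 passing shares appeared without Molino replicate 2. Thinning shifted the median of all genes, on the log2 scale, by 0.35 in Molino minus Surface and -0.26 in Pachón minus Molino in gsdf-high cells, by 0.38 and -0.36 in theca-like cells, by 0.11 in Molino minus Surface in lhcgr-high cells and by 0.13 in Pachón minus Surface in macrophage-like cells. Leaving out the low-count filter shifted it by -0.18, -0.36 and 0.19 in macrophage-like cells, 0.11, -0.22 and 0.33 in theca-like cells, and 0.11 between the caves in gsdf-high cells.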

Other observations

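The gene families in the next paragraph were chosen after the result was seen.

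Other housekeeping families were also lower in cave gsdf-high cells, beside the oxidative phosphorylation genes. Of 45 proteasome subunit genes 34 fell in each cave, with medians of -1.39 in Pachón and -1.60 in Molino (camera adjusted p = 1.19e-15 and 6.57e-17, fry 0.00827 and 0.00448, and adjusted p = 0.169 and 0.111 with an estimated correlation). Of 69 mitochondrial ribosomal protein genes 11 fell in Pachón and 24 in Molino, with medians of -0.63 and -1.12. Of 24 Sm and LSM genes of RNA splicing and decay 10 and 13 fell (-1.13 and -1.39), and of 22 mitochondrial import genes 5 fell in Pachón, and 7 fell and 1 rose in Molino (-0.70 and -1.20). With an estimated correlation the lowest adjusted p of any family was 0.111. Of cytosolic ribosomal protein genes in Pachón, 2 of 85 rose and 0 fell (median -0.04, camera adjusted p = 0.586), and in Molino 31 fell (median -0.85). The 7 chaperonin CCT genes had a median of 0.01 in Pachón, and of -1.10 in Molino, where 5 fell.

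The share of UMIs from nuclear oxidative phosphorylation genes, ribosomal protein genes left out, was lower in every cave fish than in both Surface fish in endothelial-, macrophage-, smooth muscle-, stromal fibroblast- and theca-like cells. Erythrocyte- and oocyte-like cells were lower in both caves on average, but a Pachón fish lay above Surface replicate 2 in each, at 0.746% against 0.576% and 4.23% against 4.09%. In endothelial-like cells it was 2.27 and 2.31% in Surface, 1.08 and 1.05% in Pachón and 0.911 and 1.07% in Molino. In theca-like cells it was 4.68 and 4.33%, 1.85 and 1.77%, and 2.31 and 2.33%, and in smooth muscle-like cells 2.298 and 2.31%, 1.08 and 1.15%, and 1.22 and 1.42%.

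Liver-like cells of Molino replicate 1 held apoa1b at 38008 CPM, and gsdf-high and lhcgr-high cells of the same fish held it at 23.2 and 29.4 CPM. The complement gene c1qb, at 615 and 1019 CPM in macrophage-like cells of the Surface fish, stood at 0.3 and 3.14 CPM in their gsdf-high cells.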
